A study of Bos taurus with 3 samples.

How the data were processed

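Mammary gland tissue was taken from 3 primiparous Holstein cows in mid-lactation, 1 per group, per the labels. The groups were a healthy control cow, a cow inoculated with Staphylococcus aureus and a cow inoculated with Streptococcus uberis. The S. aureus inoculum was 5 mL at 1000000 CFU/mL, and the S. uberis dose is not given in the sources used here. Infected tissue was sampled 24 h after inoculation. The labels mention infected and uninfected glands of the udder, but each array was labelled with only 1 state, and the control array was labelled as tissue of a healthy cow.

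Total RNA was extracted with Trizol, amplified, labelled with Cy3 and hybridized to 1-colour Agilent arrays, 1 sample per array, per the labels' protocols. Agilent Feature Extraction 10.7.1.1 was used, per the submitters' processing notes. The background correction and the normalization software are not given in the sources used here. The deposited values were treated as log2 signals. The base of the logarithm is not stated, and log2 was taken from the values, which ran from 0.82 to 18.92 with a median of 4.14, a range that a scanner signal would not have on a linear, natural log or log10 scale. All fold changes rest on that reading of the scale. The sorted values of the 3 columns differed by at most 0.00072, so the deposited values had been quantile normalized across the arrays over all 63134 rows, control probes included. A shift of all probes on 1 array, real or technical, is removed by that step.

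The table holds 63078 custom probes, identified by number and by 1 of 9 ID series, and 56 control probes. It holds no gene names, and the gene table used here (RefSeq genes of assembly ARS-UCD2.0) shares no identifier with the probe IDs, so 0 probes could be named. The probe was therefore the unit of every count, and the fallback rule for named items applied: at most 2 probe IDs with the highest and 2 with the lowest difference in each comparison. The comparison of 37 gene lists, the comparison of noncoding with coding probes and the spread between probes of 1 gene all need probe names and were not run.

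The comparisons, the filter on dim probes, the 2-fold threshold, the naming rule and most alternatives were chosen before the data were examined. The comparisons were S. aureus minus control, S. uberis minus control and S. aureus minus S. uberis, each a difference of the deposited log2 values. A probe was counted if the higher of the 2 arrays was above that array's median over all probes. With 1 array per group no test between groups could be made, no p-value is given, and every difference describes these 3 arrays. The number of arrays limits the precision, and nothing in the data measures the spread between cows or between arrays of the same RNA.

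The agreement of both infections was measured with Pearson's r and Spearman's rho across probes that were above the median on at least 1 array. Both differences use the same control array, so the 3 values of each probe were also assigned to the 3 groups at random, in 100 relabellings, and the overlap of independent lists was computed. Each probe was relabelled on its own. The ranges of the relabellings therefore treat probes as independent and hold no spread between arrays. Dim signals were judged against a floor of 2.09, the negative control probe of the control array plus 1 log2 unit. Where the dimmer array of a named probe lay under the floor, the fold was computed against the floor and is given as at least that fold. The counts at 16-fold and 100-fold used the deposited values without the floor. The counting step was tested on simulated arrays of 63078 probes with a noise SD of 0.3 log2 units, for S. aureus minus control. The changed probes were drawn only from probes above the median of the control array, so recovery among dimmer probes was not simulated. The counting step recovered 100% of the probes changed by 3 log2 units and 90% of those changed by 1.5. It called 1.01% of all unchanged probes, those stopped by the filter included. The noise SD was assumed and not measured, so these shares are not error rates of the counts on the real arrays.

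The alternatives were scaling each array to its 75th percentile or median, repeated quantile normalization, cyclic loess normalization, no filter on dim probes, a filter at the 75th percentile and a 4-fold threshold. Alternatives chosen after seeing the data were a shift of each infected array, or of the S. aureus array alone, to the E1A control probes, raising all values to the floor, and other numbers of bright probes. On Agilent arrays the E1A probes are designed to read added spike-in RNA. Whether spike-in RNA was added is not given in the sources used here. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.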

Results

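The series asked how RNA levels in the cow mammary gland differ between an uninfected gland and glands infected with different mastitis pathogens, on an array whose series title names long noncoding RNA. Staphylococcus aureus and Streptococcus uberis are both bacteria that infect the udder. There were 3 arrays, 1 each for the control, the S. aureus and the S. uberis gland, each with 63078 custom probes. All 3 arrays had the same median of 4.14 and the same upper quartile of 6.22 on the log2 scale, because the deposited values were quantile normalized. The share of custom probes above a background floor of 2.09 was 75.8% on every array. None of the probes could be assigned a gene, so levels are described by probe. There are no replicates, so none of the differences has an error or a test.

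Across all 63078 custom probes the S. uberis array lay closest to the control array, with Pearson's r of 0.945 and Spearman's rho of 0.924. The S. aureus and control arrays gave r of 0.894 and rho of 0.860. The arrays of the 2 infections gave r of 0.912 and rho of 0.880. Probes are not independent replicates, and the 3 correlations describe the arrays only. Among 37301 probes above the median on at least 1 array, 6489 (17.4%) spanned a 4-fold range or more over the 3 arrays. In 3769 of them (58.1%) the S. aureus array was the one farthest from the other arrays, against 33.3% if no array stood apart. The control array was farthest in 1848 (28.5%) and the S. uberis array in 872 (13.4%).

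In the S. aureus gland, compared with the control gland, 5722 of 35717 probes were at least 2-fold higher and 4986 (14.0%) were at least 2-fold lower, together 10708 probes (30.0%). At 4-fold the counts were 2410 higher and 2346 lower. At 16-fold they were 470 and 592, and at 100-fold 29 and 85, so the most extreme deposited differences were more often lower than higher. The dimmer array was under the floor for 14.1% of the probes higher and 21.3% of those lower by at least 2-fold. The filter put the brighter array above 4.14, so all of these probes also counted at 4-fold, even against the floor. They made up 804 of the 2410 higher and 1060 of the 2346 lower probes at 4-fold. The counts at 16-fold and 100-fold may therefore rest in part on values under the floor. The SD of the log2 differences over probes was 1.48. The probes with the highest differences were CUST_57206_PI429864622, at 2.73 in the control and 12.13 in the S. aureus gland (677-fold higher), and CUST_47195_PI429864031, at 1.42 and 10.68 (at least 385-fold higher). The lowest differences belonged to CUST_33413_PI429864016, which was at 14.86 in the control and 3.38 in the S. aureus gland (2858-fold), and CUST_33497_PI429864016, at 17.38 and 5.90 (2852-fold). The split between higher and lower probes rests on how the arrays are scaled. Cyclic loess normalization left it at 5773 higher and 5019 lower (53.5% higher), but it started from values that were already quantile normalized. A shift to the E1A control probes moved it, but not all other control probes shared that shift. Nor did all E1A probes. From control to S. aureus the dimmer ones went from 7.28 to 6.73, 5.39 to 4.94 and 5.03 to 5.46. The shift of -1.03 was applied to every probe, while the upper quartile of each array was 6.22. The shifted counts may therefore move dim probes too far. With the arrays shifted to the E1A control probes, an alternative chosen after seeing the data, the median difference moved to 0.98, 17399 probes were higher and 2307 were lower, and the share of higher probes among those that differed went from 53.4% to 88.3%.

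Among the 200 brightest probes of the control array, 10 were at least 32-fold lower on the S. aureus array. They lay between 14.86 and 18.41 in the control and between 3.38 and 8.70 in the S. aureus gland, and they were 729- to 2858-fold lower, with a median log2 difference of -10.09. On the S. uberis array the same 10 probes lay between 12.64 and 17.58, and their median difference from the control was -0.97, with 9 of the 10 lower. The other 190 probes had differences from -1.80 to 0.78 on the S. aureus array, and 187 of them lay within 2-fold of the control. None of the 200 was at least 32-fold lower on the S. uberis array. In the opposite direction, 2 of the 200 brightest probes of the S. aureus array were at least 32-fold higher than in the control, by 40.2-fold and 134-fold. These 2 probes lay at 8.76 and 10.48 in the control, 15.81 and 15.83 in the S. aureus gland, and 11.95 and 13.21 in the S. uberis gland. The threshold of 32-fold and the number of bright probes were chosen after the values were seen.

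**Figure D1:**
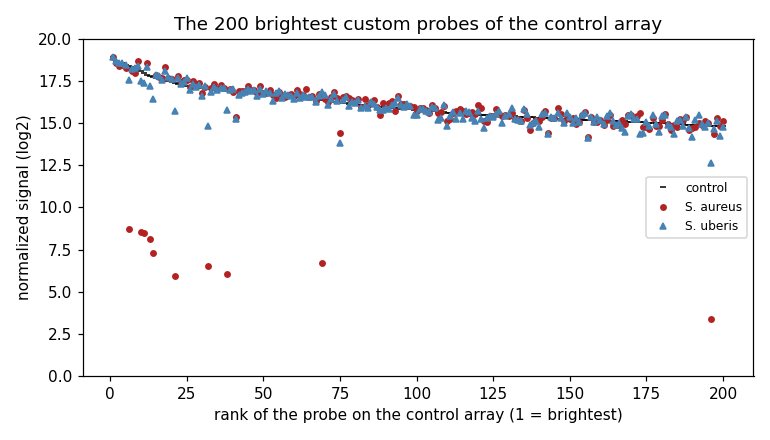
Normalized log2 signal (vertical axis) of the 200 brightest custom probes of the control array, ranked by their control signal (horizontal axis), on the control (dashes), S. aureus (circles) and S. uberis (triangles) arrays. On the S. aureus array 10 probes lie between 3.38 and 8.70, while on the S. uberis array the same probes lie between 12.64 and 17.58.

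In the S. uberis gland, compared with the control gland, 3739 of 34626 probes (10.8%) were at least 2-fold higher and 3110 (8.98%) were at least 2-fold lower. The counts at 4-fold were 991 higher and 887 lower, at 16-fold 89 and 104, and at 100-fold 8 and 4. The SD of the log2 differences was 0.97, against 1.48 for S. aureus. The highest differences were those of CUST_65930_PI429864622, at 2.54 in the control and 11.99 in the S. uberis gland (700-fold higher), and CUST_28438_PI429864031, at 2.73 and 11.16 (345-fold higher). The first of these was at 1.04 in the S. aureus gland and the second at 7.53. The lowest differences were those of CUST_96395_PI429864622, at 12.34 in the control and 3.72 in the S. uberis gland (393-fold), and CUST_78503_PI429864622, at 12.36 and 4.18 (289-fold). These were at 8.63 and 8.54 in the S. aureus gland. With the shift to the E1A control probes the median difference moved to 0.14, the counts were 4821 higher and 2377 lower, and the share of higher probes went from 54.6% to 67.0%.

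**Figure D2:**
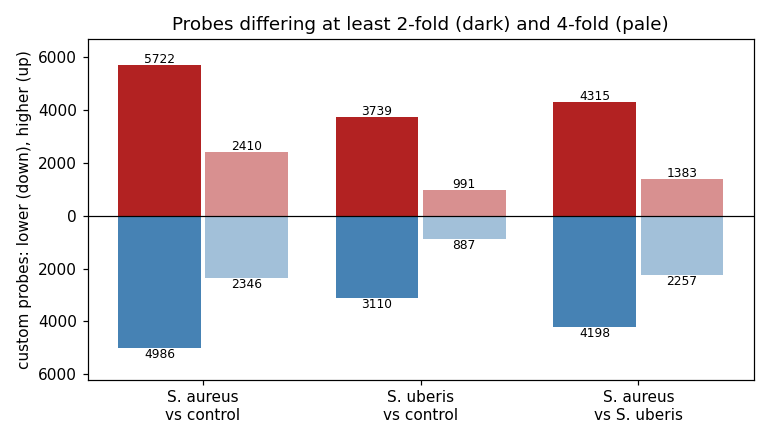
Number of custom probes that were higher (upward bars) or lower (downward bars) by at least 2-fold (dark) and at least 4-fold (pale) in each comparison, 1 array per group. The 2-fold counts are 5722 and 4986 for S. aureus against control, 3739 and 3110 for S. uberis against control, and 4315 and 4198 for S. aureus against S. uberis.

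The arrays of both infections were compared directly to ask how the response to the pathogens differs. Of 35325 probes, 4315 (12.2%) were at least 2-fold higher and 4198 (11.9%) at least 2-fold lower in the S. aureus than in the S. uberis gland. After cyclic loess normalization the larger count was the lower one, with 3982 higher and 4525 lower. The larger deposited differences were mostly lower in S. aureus. At 4-fold 1383 probes were higher and 2257 lower, at 16-fold 146 and 637, and at 100-fold 9 and 80. The dimmer array was under the floor for 10.3% of the probes higher and 26.7% of those lower by at least 2-fold. The filter put the brighter array above 4.14, so all of these probes also counted at 4-fold, even against the floor. They made up 444 of the 1383 higher and 1121 of the 2257 lower probes at 4-fold. The excess of lower probes at 16-fold and 100-fold may therefore rest in part on values under the floor. The highest differences were those of CUST_47195_PI429864031, at 10.68 in the S. aureus and 2.56 in the S. uberis gland (278-fold), and CUST_94293_PI429864622, which was at 8.76 in the S. aureus and 0.93 in the S. uberis gland (at least 102-fold). The lowest were those of CUST_95719_PI429864622, at 0.97 in the S. aureus and 12.42 in the S. uberis gland (at least 1288-fold), and CUST_65930_PI429864622 (at least 958-fold). CUST_95719_PI429864622 was at 12.14 in the control gland. With the shift to the E1A control probes the median difference moved to 0.90, the counts were 15349 higher and 2446 lower, and the share of higher probes went from 50.7% to 86.3%. The dimmer E1A probes did not share that full shift.

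The differences of both infections from the control were correlated across 37301 probes, with Pearson's r of 0.502 and Spearman's rho of 0.503. Both differences share 1 control array, which gives a correlation without any shared effect. When the 3 values of each probe were assigned to the groups at random, r ranged from 0.488 to 0.515 in 100 relabellings. The observed covariance of 0.716 lay below the 0.775 to 0.831 of the relabellings. At least 2-fold higher in both infections were 2183 probes, against 655 for independent lists and 1931 to 2102 in the relabellings. At least 2-fold lower in both were 1961 probes, against 481 for independent lists and 2185 to 2385 in the relabellings. The 2183 probes were 51.9% of the 4210 that were higher in S. uberis, and the 1961 were 60.6% of the 3238 that were lower. A single control array cannot be split, so part or all of the excess over independent lists may come from the shared control. In opposite directions, 805 probes were lower in the S. aureus and higher in the S. uberis gland, and 87 were higher in the S. aureus and lower in the S. uberis gland, against 367 to 458 and 367 to 457 in the relabellings. The relabellings treat probes as independent, so their ranges are too narrow to stand for 3 arrays. They also make the arrays alike: 5543 probes were lower in S. aureus and 3238 in S. uberis, against relabelled means of 4635 for each.

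**Figure D3:**
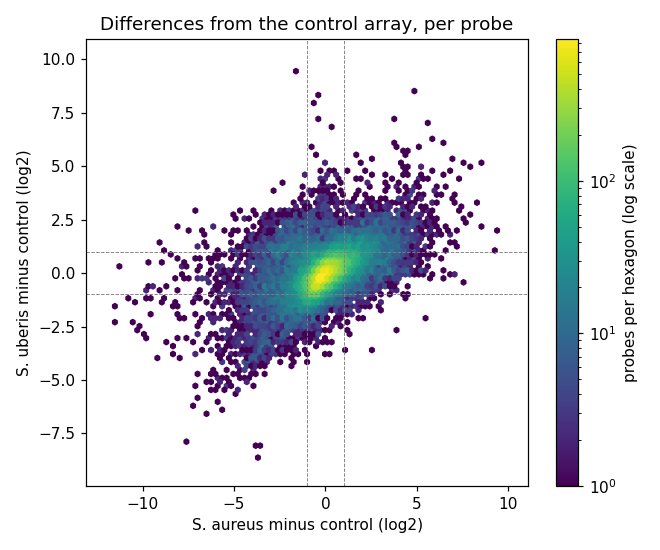
Log2 difference from the control array in the S. aureus gland (horizontal axis) and in the S. uberis gland (vertical axis) for 37301 custom probes, coloured by the number of probes per hexagon on a log scale, with dashed lines at 2-fold. The upper left field, lower in S. aureus and higher in S. uberis, holds 805 probes, and the lower right field holds 87.

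Dim probes differed more often than bright ones. By mean signal over the 3 arrays, the share at least 2-fold different between S. aureus and control was 31.6% among all custom probes with a mean of at most 4, with no filter, and 14.8% among those above 10. For S. uberis against control the shares were 26.3% and 10.5%, and for S. aureus against S. uberis 31.8% and 8.79%. The dimmer of the 2 arrays was under the background floor for 804 (14.1%) of the probes higher and 1060 (21.3%) of those lower in S. aureus than in control. The shares were 6.15% and 10.3% for S. uberis against control, and 10.3% and 26.7% for S. aureus against S. uberis. For such probes the direction is measured and the fold against the floor is a lower bound. The deposited fold is larger and rests on a value under the floor. The counts at 16-fold and 100-fold used deposited folds, so they may be too high.

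The control probes of the array did not share a level after normalization. Of 10 E1A probes, 7 were above the background floor on all 3 arrays, and 6 of these 7 were lower on the S. aureus array. Their median difference was -1.03, with a range of -1.15 to 0.43. On the S. uberis array their median difference was -0.18. Of 18 DCP probes, 16 were above the floor, with differences from -1.15 to 0.16 on the S. aureus array. The 5 DCP_1 probes among them, at 10.10 to 13.92 on the control array, lay between -1.15 and -1.10 on the S. aureus array and between -0.30 and 0.05 on the S. uberis array. The 11 DCP_20 and DCP_22 probes, at 3.66 to 7.22 on the control array, had median differences of -0.46 on the S. aureus and -0.30 on the S. uberis array. The 5 of 12 ERCC probes above the floor had a median difference of 0.24 on the S. aureus array, with both signs among them. The bright corner spot was at 17.70, 18.21 and 18.00, and the negative control probe at 1.09, 1.01 and 1.01, on the control, S. aureus and S. uberis arrays.

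**Figure D4:**
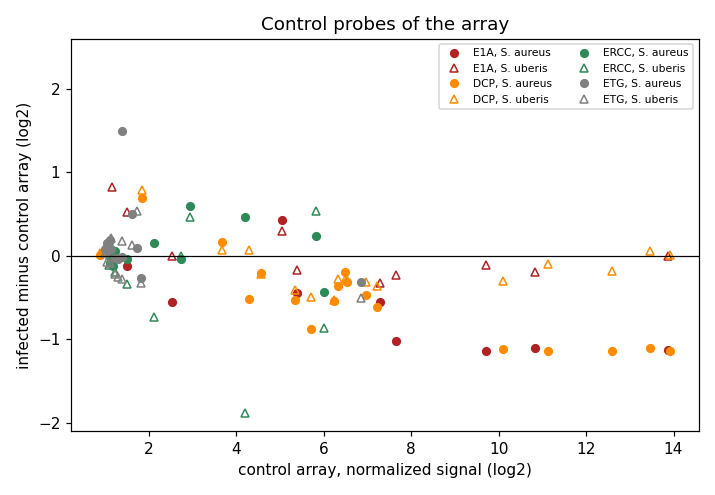
Log2 difference of each infected array from the control array (vertical axis) against the log2 signal on the control array (horizontal axis) for the E1A, DCP, ERCC and ETG control probes, filled for S. aureus and open for S. uberis. The 7 E1A probes above the background floor on all 3 arrays have a median difference of -1.03 on the S. aureus and -0.18 on the S. uberis array.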

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

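All tests in this part were chosen after the results were seen. The probes lack gene names, so no explanation that involves a pathway or a cell type was tested.

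Of the probes that differed at least 2-fold from control in both infections, 805 were lower in S. aureus and higher in S. uberis and 87 were the reverse, a ratio of 9.25. These probes drew attention because the infected arrays differed from control in opposite directions. Random relabelling of the 3 values of each probe gave 367 to 458 and 367 to 457, ranges that treat probes as independent and hold no spread between arrays. With 1 array per group the difference between the infections itself was not tested. Dim probes falling to the background on the S. aureus array cannot be the whole cause, because among probes whose mean over the 3 arrays was above the 75th percentile the counts were 126 and 5, a ratio of 25.2. The overall scale of the S. aureus array stays open: shifting that array alone to the E1A control probes gave 419 and 300, a ratio of 1.40, but raising 1 array lowers this ratio by construction. With both infected arrays shifted the counts were 495 and 192, a ratio of 2.58. After cyclic loess normalization they were 905 and 62, a ratio of 14.6. A difference between the cows or pieces of tissue and an effect of the pathogens cannot be told apart with 1 array per group.

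The probe CUST_65930_PI429864622 was at 1.04 in S. aureus and 11.99 in S. uberis, with 2.54 in the control, and drew attention as lower than control in one infection and higher in the other, which was not tested. The S. aureus value is under the background floor of 2.09, so the deposited difference of -10.95 stands for at least 958-fold, and the control lies close to the floor. The control probe ETG09_35454, outside the comparisons of custom probes, was at 2.87 on the S. aureus and 1.38 on the control array. The deposited difference is 1.497, but the control value is under the floor, and against the floor the difference is at least 0.79.

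The 10 bright probes that were far lower on the S. aureus array differed from control by -9.51 or below. The lowest difference among the other 190 brightest probes was -1.80. Those 190 exclude every probe at least 32-fold lower, and quantile normalization gives all arrays the same top values. The value of -1.80 therefore cannot decide about scaling or saturation before normalization. In control signal the 10 lay among the other 190, so a shift set by brightness alone would not separate them. A fault of the S. aureus array alone stays open, because there was 1 array per group and no repeat array of the same RNA. On the S. uberis array the 10 had a median difference of -0.97. The central 95% of random lists of 10 from the same 200 probes lay between -0.208 and 0.201. The 10 were picked as high on the control array against the S. aureus array, and the random lists were not. The lists also treat probes as independent, so their range is no fair yardstick for the 10. The difference of -0.97 uses the same control array and is far smaller than the drop on the S. aureus array. It therefore does not settle whether a fault caused or added to the drop. A difference between cows or pieces of tissue also stays open beside an effect of infection, since each group was 1 cow.

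The E1A control probes were lower on the S. aureus array, at a median of -1.03, than custom probes of the same brightness, where the medians of the central 95% of random lists of the same size lay between -0.602 and 0.629 and 0.11% of lists were as low. The quantile normalization holds the custom probes near no difference at every brightness, so this comparison cannot decide about a shift with brightness. Among the control probes the bright DCP_1 probes had a median of -1.14, and the dimmer DCP_20 and DCP_22 probes had -0.46. More labelled sample RNA per spike-in on the S. aureus array, whether from the tissue or from pipetting, could lower these probes, and this stays open with 1 array per group. One of the 7 probes, the dimmest of them on the control array at 5.03, was higher, by 0.43.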

How the results depend on the processing

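The counts of bright probes and of opposite movements, the shift to the E1A control probes and the floor were chosen after seeing the data. Scaling to the 75th percentile or the median and repeated quantile normalization moved no difference by over 0.00048, as the values were already quantile normalized, so they say nothing about stability. Cyclic loess normalization kept every count of higher, lower and shared probes within 1.5 times. It started from the quantile normalized values, so a shift removed by that step could not return. It is therefore a weak check of stability. The 12 named differences kept their direction and stayed at least 2-fold in all 36 combinations with cyclic loess normalization, the E1A shift or the floor, with absolute log2 values from 6.67 to 11.48. The 12 were picked as the most extreme differences, far larger than the E1A shift. That outcome was close to fixed in advance and says little about stability. In the order S. aureus against control, S. uberis against control and S. aureus against S. uberis, counts of higher and lower probes without a filter were 9185 and 8265, 6901 and 6064, and 8047 and 7461, with 3196 probes lower in both infections. Above the 75th percentile they were 2714 and 2095, 1636 and 1247, and 1759 and 1657, with 1170 higher in both, 842 lower in both, 305 lower in S. aureus and higher in S. uberis, and 21 the reverse. At 4-fold they were 2410 and 2346, 991 and 887, and 1383 and 2257, with 501, 640, 96 and 4 in the same order. The filters and the threshold set these counts by their construction. After the E1A shift the S. aureus array had 17399 higher and 2307 lower than control and 15349 and 2446 against S. uberis, with 3888 higher in both, 1045 lower in both, and 495 and 192 in opposite directions, since the shift moves all probes of an array by 1 value. The dimmer E1A probes did not share that full shift on the S. aureus array. With the S. aureus array alone shifted the opposite counts were 419 and 300. With all values raised to the floor 2027 probes were higher in both infections and 1961 lower in both, with 661 and 62 in opposite directions. Among the brightest 500 probes 17 of the control array were far lower on the S. aureus array, and 9 of the S. aureus array far higher than control. Alternatives that average the probes of a gene, use unmatched gene lists or change an offset before the logarithm were not run, because no probe could be named and the values were already logarithms. With 1 array per group no array could be left out. Signal over background limits the folds of dim probes. Only those computed against the floor are lower bounds.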

Other observations

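The comparison in this part was chosen after seeing the data, and no explanation was tested. Custom probe IDs end in 1 of 9 series numbers. The median difference from control of each series was set against 10000 random lists of the same size matched on mean signal. For each infection 4 series lay above the central 95% of the random lists, 4 below and 1 inside, and the series on each side were the same for both infections, which share the control array. The medians use all probes of a series, and the shares below use only its probes above the median on at least 1 array. In series PI429864016, with 4422 probes, the S. aureus minus control median was 0.15, against -0.0567 to -0.0165 in the central 95% of the random lists. Of its 3516 probes above the median, 20.8% were at least 2-fold higher and 10.6% at least 2-fold lower. In series PI429864633, with 9317 probes, the median was -0.12, against -0.0237 to 0.0135. Of its 5302 probes above the median, 12.4% were higher and 18.3% lower. Between S. aureus and S. uberis, a comparison without the control array, 2 series lay above, 4 below and 3 inside. What the series numbers stand for is not given in the sources used here.

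The 10 bright probes that were far lower on the S. aureus array came from 4 of the 9 ID series. Of the 200 brightest probes of the S. uberis array, 9 were at least 32-fold lower on the S. aureus array and 0 were that far lower on the control array. These were 9 of the same 10 probes, so the count is not a separate finding. The remaining probe, CUST_33413_PI429864016, was at 12.64 on the S. uberis array and not among its 200 brightest. The 805 probes that were lower in S. aureus and higher in S. uberis had median signals of 4.12 in the control, 1.60 in the S. aureus and 5.77 in the S. uberis gland, and 492 of them (61.1%) were under the background floor on the S. aureus array.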
